A study of Mus musculus with 6 samples.

How the data were processed

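The data were whole-number read counts per gene for 6 libraries of amygdala neurons, 3 from mice with sgRosa and 3 from mice with sgEgfr, grouped by the titles of the samples. The authors deposited raw counts per gene with no normalization: one table per library and one table of the whole series, whose 6 matching columns were identical to the separate tables gene by gene. A further 3 columns of that table matched no sample description and were not used in any step. Per the submitters' processing notes, the tools were fastp 0.23.2, STAR 2.7.5c, featureCounts 2.0.1, edgeR 3.42.4, FastQC 0.11.9 and MultiQC 1.11 with the mm10 genome build; the order of the steps, the options, the gene annotation and the strand setting were not given in the sources used here. Per the labels' protocols, tissue was digested with papain, neurons were enriched with a magnetic adult neuron isolation kit, RNA was extracted with a PicoPure kit and libraries were made from 5 ng of RNA with a NEBNext kit. Such small inputs are amplified by PCR, and the counts carry no molecular identifiers, so values at low counts cover counting error only. The labels number the libraries within each group and do not say whether each came from a separate animal, so p-values measure the spread between these libraries.

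The counts held 35976 genes, of which 13159 passed edgeR's filterByExpr (minimum count 10, minimum total count 15) and were tested. Total counts ranged from 2348897 to 10152812. Libraries were scaled by TMM, dispersions were estimated robustly, and sgEgfr was compared with sgRosa by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of the log2 fold changes of single genes were derived from the fold change and the F statistic. Those set beside list medians are of the group difference in the list's mean log2 CPM. CPM values are TMM-scaled and are given with the SD over 3 libraries. The common biological coefficient of variation was 0.355. No pair of libraries agreed within sampling noise (the lowest chi-square per degree of freedom was 10.0), so none was taken for a second deposit of another. This does not show that the libraries came from separate animals.

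The genes reported were set by a rule before the data were examined. Egfr, Areg, Nr2f2, Rbfox3 and Aqp4 were always to be given. Up to 12 genes per direction that passed, had a mean log2 CPM of at least 1 and had separated groups came next, filled up to 12 by the smallest unadjusted p as genes that did not pass; symbols of predicted genes were passed over, which left out 3 higher and 0 lower genes. From each gene list up to 4 members with the smallest unadjusted p could be named. At most 3 are given, a number set after the data were examined, and some of these members are left out of the text. Gene positions and exon overlaps come from the GENCODE annotation of GRCm38, the assembly that mm10 names; a position is given for the genes described in most detail. Genes Ttr and Mbp in the closing section were chosen after their values were seen.

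Gene lists for cell types, brain regions and cellular programmes, 44 in all, were fixed before the data were examined and tested on log2 CPM (prior count 2) with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. All 646 list genes were found in the counts, with mitochondrial genes matched under their older symbols, and every list had at least 5 tested members. The list of COUP-TF genes and the choice of Nr2f2 rest on knowledge of the study's published account.

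Alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 20 counts), DESeq2 1.42.0, limma-voom with quality weights, the legacy quasi-likelihood fit, a replicate block, a test against a fold of 1.2, an adjusted p under 0.1, and leaving out each library in turn. The pan-neuronal mean of each library as a covariate, leaving out the 2 libraries with choroid plexus RNA (sgRosa replicate 3 and sgEgfr replicate 1), and the removal of each library's trend on transcript length (lowess span 0.3) were chosen after seeing the data. Transcript lengths were matched for 95.6% of the tested genes and for all 30 ribosomal protein genes.

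In the closing section some tests were changed after their first values were seen. The depth test went from 1 thinning draw to 10, and the spread set beside it went from that between libraries to that over the draws. For the ribosomal and Nr2f2 tests the margin of 1 SE was first taken from 0, or not taken, and then from the bound written in advance. That change turned the reading of the ribosomal test with the pan-neuronal covariate from against the explanation to open. The oxidative phosphorylation test with that covariate first asked for a median below -0.3 by 1 SE, which the uncorrected median of -0.34 would not have met with that SE either. It then asked for a median at or below -0.3 that lies below -0.15 by 1 SE, which turned its reading from open to against the explanation, while the ribosomal reading stays open by either margin. Because this change followed the value, the explanation is not taken as excluded. The test of the RNA of all other cells went from monocyte to red blood cell genes, both relative to oligodendrocyte markers, which turned its reading from open to against the explanation. Because the red blood cell genes were picked after their value was seen, the explanation is left open. The endothelial test went from the marker difference alone to a fit with the endothelial mean as a covariate, which turned its reading from open to against the explanation. That mean hardly differed between the groups, so the fit is not taken as deciding.

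The tests were tried on simulated counts drawn from the real means, depths and dispersions, with 200 changed genes. These were taken only from genes with a mean of at least 20 counts. In the sgEgfr against sgRosa simulation, run on 12798 genes, the quasi-likelihood test recovered 3 of 67 genes changed 2-fold, 45 of 67 changed 4-fold and 62 of 66 changed 8-fold, with 12 false calls; DESeq2 recovered 7, 53 and 62 with 31 false calls and limma-voom 2, 43 and 57 with 8 false calls. A simulated list of 20 genes shifted by 1 log2 unit had an adjusted p of 9.08e-11 with the preset correlation and 0.186 with the estimated one, and 0 of 43 unchanged lists were called by either. The simulated genes were drawn independently of one another. These lists therefore do not show how often the preset test calls unchanged lists whose genes are correlated, as in the real data.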

Results

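Neurons from the amygdala of male C57BL/6J mice were profiled by bulk RNA sequencing after astrocytes were targeted by CRISPR. The mice carried an adeno-associated virus in which the astrocyte promoter GfaABC1D drove Cas9, with guides against Egfr (the epidermal growth factor receptor) or against Rosa, a control locus. After more than 2 weeks of expression they went through 7 days of restraint, then fear conditioning (1 day) and extinction training (3 days). Neurons were isolated magnetically from the dissociated tissue. The data hold 3 sgRosa and 3 sgEgfr libraries, each made from 5 ng of RNA. Total counts were 4144701, 2348897 and 10152812 in sgRosa replicates 1, 2 and 3, and 4849404, 4352966 and 2520426 in sgEgfr replicates 1, 2 and 3. A floor of 3 counts in one library corresponded to between 0.270 and 1.25 CPM (counts scaled to library size). These floors cover counting error only.

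The targeted gene was low in every library. Egfr (chromosome 11, 16752203 to 16918158, plus strand, mm10) had 1, 26 and 23 counts in the sgRosa libraries and 6, 18 and 6 counts in the sgEgfr libraries, and its log2 fold change of -0.64 (SE 1.01) lay within the spread between replicates. Without sgRosa replicate 2 the log2 fold change of Egfr was 0.95. The sequenced cells were enriched for neurons and not for the astrocytes that carried Cas9. Astrocyte RNA was still present, with marker means of 5.22 log2 CPM in sgRosa and 5.02 in sgEgfr. The cells that gave the Egfr reads are not known. Cas9 edits can also disrupt a protein without lowering its RNA, so these counts do not check the knockdown. Areg, which encodes the EGFR ligand amphiregulin, had at most 6 counts in any library and was filtered out. The neuronal gene Rbfox3 had a log2 fold change of 0.52 (edgeR adjusted p = 0.846) and the astrocyte water channel gene Aqp4 of -0.14 (adjusted p = 0.971), neither beyond the spread between replicates. The value for Rbfox3 was 1.25 without sgRosa replicate 3, 0.29 without sgRosa replicate 1 and 0.32 without sgRosa replicate 2, and 1.17 by limma-voom (adjusted p = 0.250, against 0.122 to 0.999 over all alternatives). Without sgRosa replicate 2 the value for Aqp4 was 0.39 and without sgEgfr replicate 3 it was 0.31.

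The comparison of sgEgfr with sgRosa asks how gene expression in neurons of stressed mice differed when neighbouring astrocytes carried guides against Egfr. Nr2f2, a nuclear receptor transcription factor of the COUP-TF family, averaged 57.9 ± 5.17 CPM in sgRosa and 111 ± 16.0 CPM in sgEgfr (SD, n = 3 each), and all 3 sgEgfr libraries lay above all 3 sgRosa libraries. Higher levels with the same separation were measured for the synaptic adhesion gene Slitrk2 (9.70 ± 2.32 against 58.3 ± 28.8 CPM), the cell cycle kinase gene Cdk6 (24.9 ± 1.61 against 64.6 ± 9.67 CPM), the interferon-induced antiviral gene Rsad2 (17.2 ± 8.27 against 81.6 ± 33.5 CPM) and the histone methyltransferase gene Kmt2d (109 ± 8.47 against 238 ± 11.2 CPM). Lower levels were measured for neuropeptide genes: somatostatin (Sst) averaged 39.0 ± 22.2 CPM in sgRosa and 9.47 ± 2.62 CPM in sgEgfr, neuropeptide Y (Npy) 15.8 ± 7.00 against 4.91 ± 0.629 CPM, and proenkephalin (Penk) 113 ± 67.3 against 28.9 ± 16.0 CPM. By edgeR and limma-voom none of these differences passed over all 13159 genes. By DESeq2 all of them passed except those of Penk, which did not pass, and Npy, which had no defined adjusted p.

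**Figure D1:**
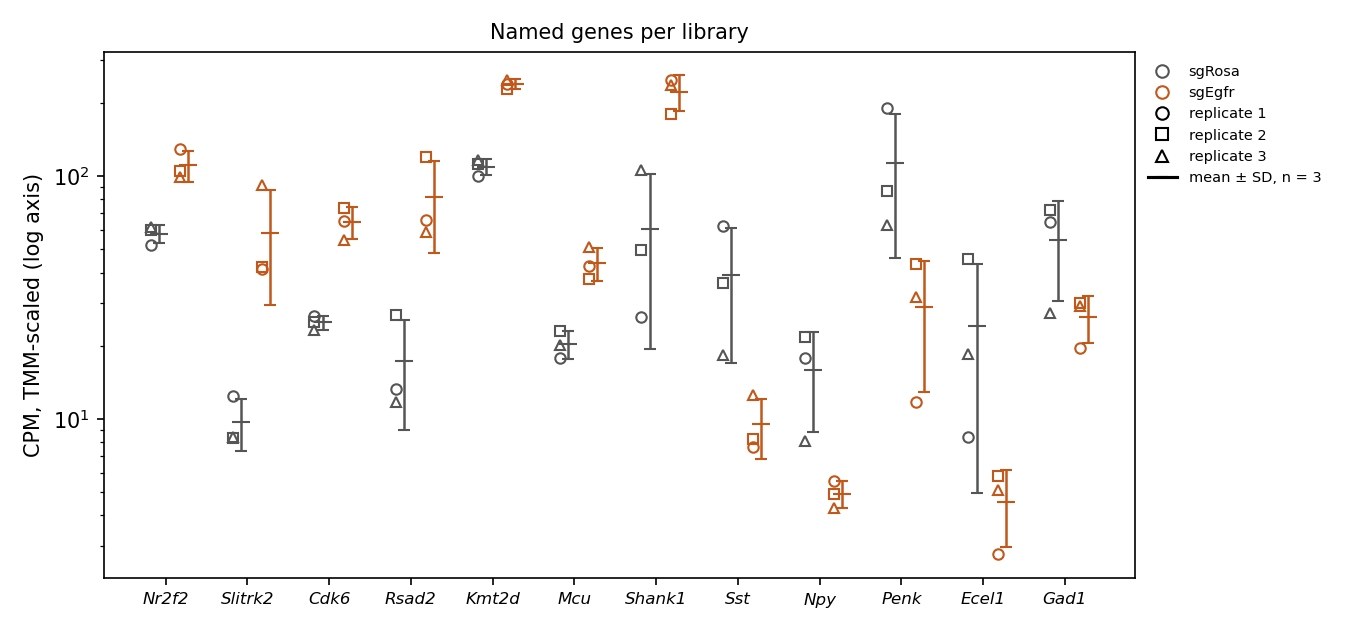
TMM-scaled CPM on a log axis for 12 genes in each library, with symbols for the replicate number and bars for the mean ± SD of 3 libraries; gray is sgRosa and orange is sgEgfr. For Nr2f2 the sgRosa libraries average 57.9 CPM and the sgEgfr libraries 111 CPM with no overlap, while for Gad1 the ranges overlap.

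By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes were higher and 0 lower in sgEgfr, and the smallest adjusted p was 0.781. At an unadjusted p under 0.05 there were 811 genes, 425 higher and 386 lower, where chance gives about 658. The limma-voom test gave 0 genes in either direction (1978 at an unadjusted p under 0.05), and DESeq2 gave 31 higher and 2 lower genes (787 at an unadjusted p under 0.05), with an undefined adjusted p for 5114 genes. The 2 genes called lower by DESeq2 were Sst (adjusted p = 0.0381) and the proopiomelanocortin gene Pomc (adjusted p = 0.0215), which had log2 fold changes of -2.05 and -4.27 in the edgeR fit. Pomc was at 132 CPM in sgRosa replicate 2 and at or below 9.84 CPM in the other libraries, and without that library its log2 fold change was -1.47. The groups did not overlap for 1763 genes, 13.4% of those tested, where chance gives 10%. In simulated counts with the same depths and dispersion the quasi-likelihood test recovered 4.48% of genes changed 2-fold, 67.2% of those changed 4-fold and 93.9% of those changed 8-fold. The quasi-likelihood test made 12 false calls there. The changed genes came only from genes above a minimum mean count, and all genes were drawn independently of one another. Recovery also depends on how many genes change, so these shares need not hold for the real counts. DESeq2 recovered 10.4%, 79.1% and 93.9% with 31 false calls, so some of its calls in the real counts may be false. Those false calls stood beside 7, 53 and 62 recovered genes. The number of false calls depends on how many genes change, which is unknown in the real counts.

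Nr2f2 (chromosome 7, 70351944 to 70366735, minus strand) had a log2 fold change of 0.94 (SE 0.22), ranked 19th of the tested genes by p and had an adjusted p of 0.781 by edgeR and 0.0381 by DESeq2 (0.0381 to 0.999 over all alternatives). Adjusted over the 4 tested genes that were always to be reported, its p was 0.0114; Nr2f2 was placed among them from knowledge of the study's published account, so that value is not independent evidence. The 12 genes with the smallest p among those higher in sgEgfr, none of which passed by edgeR, ranged from Slitrk2 (chromosome X, 66649318 to 66661393; log2 fold change 2.58, SE 0.39) to the nuclear receptor corepressor gene Nrip1 (0.99, SE 0.23). Between them lay Cdk6 (1.38), Rsad2 (2.26), Kmt2d (1.13), Pisd-ps3 (1.83), the chemokine receptor gene Ccr7 (2.35), Chic1 (1.25), the mitochondrial phosphatase gene Ppm1k (1.17) and the vesicular monoamine transporter gene Slc18a2 (1.23). The remaining 2 were Dennd5b (2.15-fold) and the mitochondrial calcium uniporter gene Mcu (2.16-fold). DESeq2, run on the same counts, called 10 of these 12. The value for Ccr7 rests on few reads, at 0.844, 2.09 and 1.80 CPM in the sgRosa libraries. The floor of 3 counts was 0.844 CPM in sgRosa replicate 1. The DESeq2 adjusted p of Ccr7 was undefined. Pisd-ps3 is annotated as a pseudogene, and reads shared with its parent gene were not separated.

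The 12 genes with the smallest p among those lower in sgEgfr, none of which passed by edgeR, included Sst (chromosome 16, 23889573 to 23890958; log2 fold change -2.05, SE 0.46), Npy (-1.65, SE 0.41), Penk (-1.97, SE 0.56) and Ecel1 (-2.39, SE 0.62), which encodes a neuronal membrane peptidase. The others were the minor spliceosome gene Zmat5 (-0.93), the retinoid X receptor gene Rxrg (-1.11), the mitochondrial ribosomal gene Mrps21 (-1.04), Nenf (-0.77), Mad2l2 (-1.12), the G protein subunit gene Gng7 (-1.20), Rpp25l (-1.36) and C1galt1c1 (-0.81). All 24 genes had separated groups, which the choice by smallest p in the same libraries favours, so the separation is not further evidence. Exons of Nr2f2, Cdk6, Dennd5b, Slc18a2, Zmat5 and Penk overlap exons of a gene on the opposite strand, and the strand setting of the counting was not given in the sources used here, so reads of the 2 genes could not be told apart.

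Libraries differed in their makeup in ways that only partly followed the groups. The mean log2 CPM of pan-neuronal genes was 6.58, 6.56 and 7.79 in the sgRosa libraries and 7.56, 7.07 and 7.79 in the sgEgfr libraries, so that sgRosa replicate 3 lay at the level of the highest sgEgfr library. Oligodendrocyte markers averaged 10.53, 9.86 and 8.73 in sgRosa and 9.10, 9.65 and 8.04 in sgEgfr. Mitochondrially encoded transcripts took 29.8% of counts in sgRosa replicate 1 and between 10.3% and 15.7% in the other 5 libraries.

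Of 44 gene lists fixed before the data were examined, 21 passed an adjusted p of 0.05 in the camera test with the preset correlation of 0.01, 14 toward higher and 7 toward lower expression in sgEgfr. With an estimated correlation 0 passed (smallest adjusted p = 0.691), and fry's direction test and its mixed test also gave 0 lists (smallest adjusted p = 0.720 and 0.592). Without sgRosa replicate 1 the preset test passed 12 lists, and 7 of the 21 passed without each library in turn: inhibitory neuron markers, red blood cell genes, central and medial amygdala markers, neuropeptides, NF-kB and cytokine genes, oxidative phosphorylation genes and ribosomal proteins. No member of any list passed over all genes tested by edgeR, and 11 list memberships passed when p was adjusted over the list alone.

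**Figure D2:**
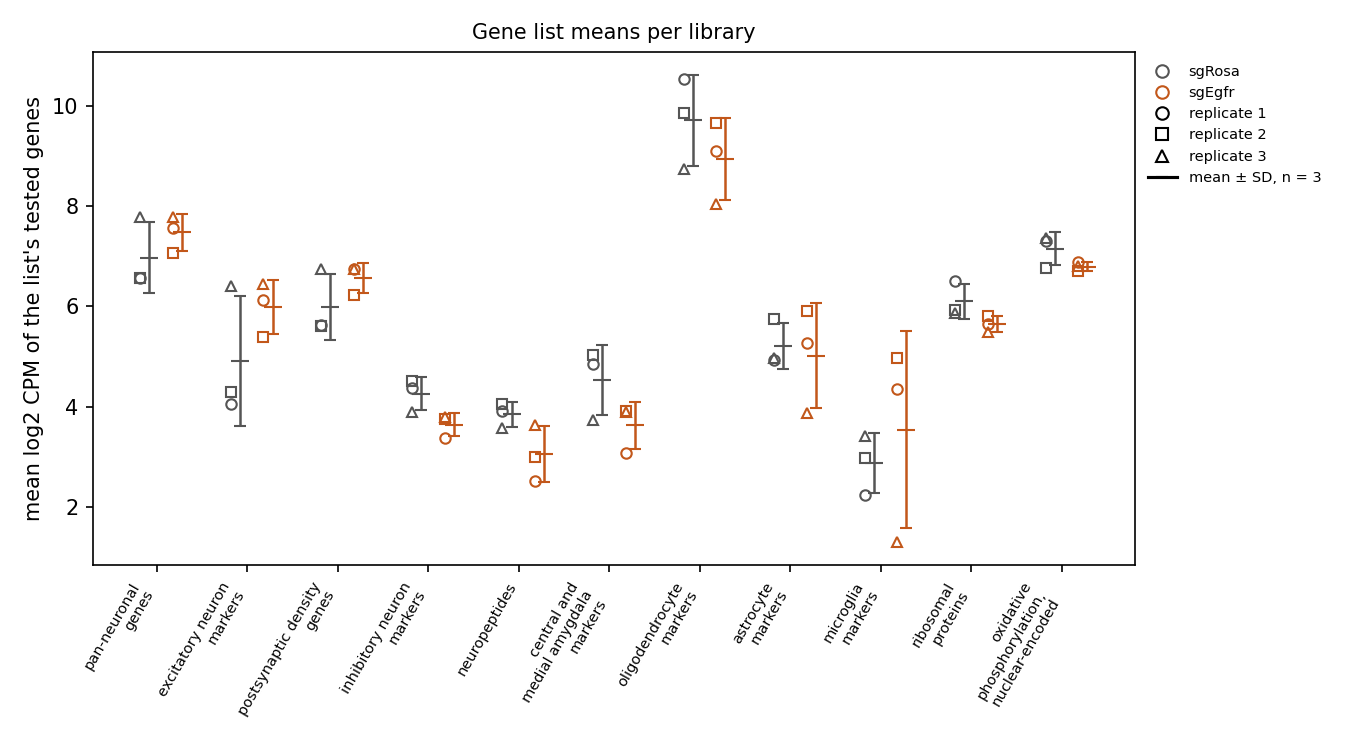
Mean log2 CPM of the tested genes of 11 lists in each library, with symbols for the replicate number and bars for the mean ± SD of 3 libraries; gray is sgRosa and orange is sgEgfr. For the pan-neuronal genes sgRosa replicate 3 (7.79) lies apart from sgRosa replicates 1 and 2 (6.58 and 6.56) and among the sgEgfr libraries.

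All 16 pan-neuronal genes had positive log2 fold changes (median 0.41, adjusted p = 0.00226; adjusted p = 0.691 with an estimated correlation), with the smallest p for the RNA-binding gene Elavl4 (1.06), Eno2 (0.66) and Nefm (0.71). All 11 tested excitatory neuron markers were positive too (median 0.82, adjusted p = 6.81e-04; adjusted p = 0.691 with an estimated correlation), with the smallest p for the postsynaptic gene Nrgn (0.76) and the vesicular glutamate transporter gene Slc17a7 (0.69). Postsynaptic density genes were positive in 19 of 20 (median 0.42, adjusted p = 5.08e-04; adjusted p = 0.691 with an estimated correlation) with the scaffold gene Shank1, which DESeq2 called, at 1.87 and Homer1 at 0.48. Synaptic vesicle genes were positive in 16 of 20 (median 0.43, adjusted p = 0.00345; adjusted p = 0.691 with an estimated correlation) with Cplx2 at 0.77, Vamp2 at 0.47 and Syn2 at 0.73. Synaptic adhesion genes were positive in 15 of 21 (median 0.25, adjusted p = 0.0433; adjusted p = 0.705 with an estimated correlation) with Cntn4 at 0.77 and Cntnap2 at -0.36. Voltage-gated potassium channels were positive in 15 of 16 (median 0.38, adjusted p = 0.00226; adjusted p = 0.691 with an estimated correlation) with Kcnq3 at 0.70 and Kcnd2 at 0.68. Voltage-gated sodium and calcium channels were positive in 16 of 18 (median 0.30, adjusted p = 0.00737; adjusted p = 0.691 with an estimated correlation) with Cacna2d3 at -0.84 and Scn2b at 1.04. GABA receptors were positive in 13 of 14 (median 0.38, adjusted p = 0.00967; adjusted p = 0.691 with an estimated correlation) with Gabrb2 at 0.90. No member of these 8 lists passed the edgeR test over all genes or adjusted over the list alone. Oligodendrocyte markers, a sign of the makeup of each library, averaged 9.71 ± 0.907 log2 CPM in sgRosa and 8.93 ± 0.818 in sgEgfr (SD, n = 3 each). The medians of the 8 lists lay between 0.0278 and 0.47 without sgRosa replicate 1, between 0.15 and 0.51 without sgRosa replicate 2 and between 0.92 and 2.15 without sgRosa replicate 3. They lay between 0.42 and 1.07 without sgEgfr replicate 2 and between 0.0930 and 0.58 without sgEgfr replicate 3. Without sgRosa replicate 2 the preset call was lost for all 8 lists, with adjusted p from 0.0507 for excitatory markers to 0.295 for synaptic adhesion. Without sgRosa replicate 1 it was lost for 6 of them, all but the excitatory and postsynaptic lists (adjusted p from 0.0849 to 0.426), and without sgEgfr replicate 3 for the vesicle, adhesion, sodium and calcium channel and GABA receptor lists (adjusted p from 0.0832 to 0.360). With the pan-neuronal mean of each library as a covariate, an alternative chosen after seeing the data, all 8 lists lost the preset call (adjusted p from 0.272 to 0.875) and 5 of them turned direction (vesicle, adhesion, sodium and calcium channels, GABA receptors and, by construction, pan-neuronal). With each library's trend on transcript length removed, also chosen after seeing the data, the sodium and calcium channel and adhesion calls were lost (adjusted p of 0.131 and 0.450).

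Of 11 tested inhibitory neuron markers 9 had negative log2 fold changes (median -0.54, adjusted p = 0.00592; adjusted p = 0.691 with an estimated correlation), with Sst and Npy passing when p was adjusted over the list alone and the GABA-synthesizing enzyme gene Gad1 at -1.05. Neuropeptide genes were negative in 11 of 13 (median -1.11, adjusted p = 0.00158; adjusted p = 0.691 with an estimated correlation), with Sst, Npy and Penk passing when adjusted over the list alone. Central and medial amygdala markers were negative in 8 of 10 (median -0.89, adjusted p = 0.00211; adjusted p = 0.691 with an estimated correlation), with Sst, Ecel1 and Penk passing when adjusted over the list alone. Striatum markers were negative in 8 of 10 (median -0.73, adjusted p = 0.00942; adjusted p = 0.691 with an estimated correlation), with the signaling gene Ppp1r1b at -0.66 and Rgs9 at -1.71. Without sgRosa replicate 1 or 2 the preset call for the striatum list was lost (adjusted p up to 0.105). With the pan-neuronal covariate the calls for the central and medial amygdala and the striatum lists were lost (adjusted p of 0.395 and 0.272). Over all alternatives their adjusted p ranged from 1.23e-04 to 0.395 and from 1.44e-04 to 0.272. The inhibitory median was -0.998 without sgRosa replicate 3 and -1.06 without sgEgfr replicate 2, and the neuropeptide median was -0.64 without sgRosa replicate 2 or sgEgfr replicate 1. The central and medial amygdala median was -1.34 without sgRosa replicate 3 and -1.40 without sgEgfr replicate 3. Ecel1 was at -1.54 without sgRosa replicate 2. Sst is a member of 3 of these lists, which are not independent of one another.

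Cortex layer markers were positive in 8 of 12 (median 0.12, adjusted p = 0.0327; adjusted p = 0.691 with an estimated correlation), with the smallest p for Cux2 (0.99), Rorb (1.17) and Ctgf (0.88). The preset call was lost without sgRosa replicate 1, sgEgfr replicate 1 or sgEgfr replicate 3 (adjusted p up to 0.272), with the stricter filter, with the length trend removed and with the pan-neuronal covariate (adjusted p from 0.00499 to 0.737 over all alternatives). The median of this list ranged from 0.0439 without sgRosa replicate 1 to 0.60 without sgRosa replicate 3, and was 0.32 without sgRosa replicate 2 and 0.39 without sgEgfr replicate 2. The list of COUP-TF and partner genes passed (adjusted p = 0.0433; adjusted p = 0.691 with an estimated correlation) with 6 of 8 members positive, among them Nr2f2, which passed when adjusted over the list alone, Bcl11a (0.79) and Nr2f1 (0.55). This list was chosen from knowledge of the study and is not independent evidence of its direction. Its call was lost without sgRosa replicate 1 or 2 or sgEgfr replicate 3 (adjusted p up to 0.295), with the length trend removed and with the pan-neuronal covariate (adjusted p from 0.00317 to 0.715 over all alternatives). Its median of 0.22 was 0.57 without sgRosa replicate 3 and 0.40 without sgEgfr replicate 1. Basolateral amygdala markers, whose median was 0.0282 with RLE scaling, were positive in 6 of 12 (median -0.00363, adjusted p = 0.681) with Rorb at 1.17 and Ppp1r1b at -0.66. Hippocampus markers were positive in 2 of 7 (median -0.19, adjusted p = 0.681) with C1ql2 at -1.05 and Neurod6 at 0.97. Hypothalamus and thalamus markers were positive in 4 of 6 (median 0.40, adjusted p = 0.681) with Pomc at -4.27 and Rora at 0.59.

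Markers of non-neuronal cells were present in all libraries. All 16 oligodendrocyte markers had negative log2 fold changes (median -0.79, adjusted p = 0.00168; adjusted p = 0.691 with an estimated correlation), with the smallest p for the myelin genes Opalin (-1.87) and Mag (-1.14) and for Aspa (-2.02). The preset call was lost without sgRosa replicate 1 or sgEgfr replicate 3 (adjusted p up to 0.162), and the direction turned with the pan-neuronal covariate. Without sgRosa replicate 1 Opalin was at -0.50, Aspa at -0.52 and Mag at -0.75, and the list median was -0.46. That median was -0.48 without sgEgfr replicate 3 and -1.36 without sgEgfr replicate 2. Oligodendrocyte precursor markers did not pass (7 of 9 positive, adjusted p = 0.0744), with Lhfpl3 at 0.95 and Vcan at 1.40. Monocyte and border macrophage markers were positive in 6 of 6 (median 0.69, adjusted p = 0.00967; adjusted p = 0.691 with an estimated correlation), with Mrc1 at 1.19, H2-Aa at 0.76 and H2-Ab1 at 0.83. The call was lost without sgRosa replicate 3 or sgEgfr replicate 2 (adjusted p up to 0.0664). Microglia markers were positive in 14 of 15 and did not pass (median 1.31, adjusted p = 0.0525), with Aif1 at 1.59 and P2ry12 at 1.82. Their means ranged from 1.31 in sgEgfr replicate 3 to 4.97 in sgEgfr replicate 2. Astrocyte markers did not pass (5 of 16 positive, median -0.16, adjusted p = 0.547), with Slc1a2 at 0.72 and the connexin gene Gjb6 at -1.14. Reactive astrocyte genes were positive in 11 of 17 (median 0.26, adjusted p = 0.0490; adjusted p = 0.691 with an estimated correlation), with the smallest p for Osmr (1.42), Lcn2 (2.32) and Cd14 (1.54). The call was lost without sgRosa replicate 1, sgRosa replicate 3 or sgEgfr replicate 2 (adjusted p up to 0.916), with RLE scaling, with the stricter filter and without both sgRosa replicate 3 and sgEgfr replicate 1. Its median was 0.0536 without sgRosa replicate 3, -0.0394 without sgEgfr replicate 2, 0.74 without sgRosa replicate 2 and 0.49 without sgEgfr replicate 1. Endothelial markers (3 of 11 positive, median -0.29, adjusted p = 0.838) with Cldn5 at -1.03 and Ly6c1 at -0.71 did not pass. Mural and fibroblast markers (2 of 11, median -0.19, adjusted p = 0.681) with Acta2 at -1.18 and Kcnj8 at -0.78 did not pass, nor did ependymal and choroid plexus markers (1 of 10, median -0.71, adjusted p = 0.483) with Foxj1 at -1.07 and Ccdc153 at -1.39. Red blood cell genes were positive in 7 of 7 (median 1.55, adjusted p = 4.97e-04; adjusted p = 0.691 with an estimated correlation), with the heme synthesis gene Alas2 at 2.41 passing when adjusted over the list alone and the hemoglobin gene Hbb-bt at 1.83. Without sgEgfr replicate 2 the list median was 0.61, Alas2 was at 1.45 and Hbb-bt at 0.61. The call was lost without both sgRosa replicate 3 and sgEgfr replicate 1, an alternative chosen after seeing the data (adjusted p = 0.0641, against 4.61e-09 to 0.0641 over all alternatives).

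Ribosomal protein genes were negative in 29 of 30 (median -0.48, adjusted p = 3.34e-08; adjusted p = 0.691 with an estimated correlation), with Rps19 at -1.12, Rpl32 at -0.98 and Rpl6 at -0.72. Without sgRosa replicate 1 the ribosomal median was -0.22. All 30 nuclear-encoded oxidative phosphorylation genes were negative (median -0.34, adjusted p = 1.54e-05; adjusted p = 0.691 with an estimated correlation), with Cox6a1 at -1.16, Ndufa2 at -0.65 and Ndufb9 at -0.67. Separated groups were found for 14 of the 30 ribosomal and 7 of the 30 oxidative phosphorylation genes, against 13.4% of all tested genes, and the estimated correlations within the lists were 0.67 and 0.585, so the members of a list do not count as independent. The 8 tested mitochondrially encoded genes were all negative but did not pass (median -0.62, adjusted p = 0.0946), with ND3 at -1.70 and COX1 at -1.06. No member of these 3 lists passed the edgeR test over all genes or adjusted over the list alone. With each library's trend on transcript length removed, an alternative chosen after seeing the data, the medians were -0.24 for ribosomal protein genes and -0.11 for oxidative phosphorylation genes, and both lists still passed with the preset correlation.

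NF-kB and cytokine genes were positive in 16 of 17 (median 0.98, adjusted p = 1.78e-05; adjusted p = 0.691 with an estimated correlation), with the smallest p for the chemokine gene Ccl5 (2.01), the adhesion gene Vcam1 (0.98) and Nfkb1 (0.96), none of which passed the edgeR test. Vcam1 and Nfkb1 lay near the median of the list. Ccl5 averaged 1.66 ± 0.832 CPM in sgRosa, near the floor, and had no defined adjusted p by DESeq2. Monocyte markers were positive in 6 of 6 and microglia markers, which did not pass (adjusted p = 0.0525), in 14 of 15. The mean log2 CPM in sgEgfr replicate 2 was the highest of the 6 libraries for the NF-kB and cytokine genes (5.49), the microglia markers (4.97) and the monocyte markers (4.43), and that of the microglia markers was lowest in sgEgfr replicate 3 (1.31). Interferon-stimulated genes did not pass the preset camera test as a list (7 of 18 positive, median -0.16, adjusted p = 0.980), although Rsad2 passed when adjusted over the list alone. Ifi27 was at -0.79. Immediate early genes (8 of 20 positive, median -0.59, adjusted p = 0.504) with Dusp1 at -0.96 and Fos at -1.33 did not pass. Dissociation-induced genes (4 of 20, median -0.66, adjusted p = 0.0749) with Hspa1b at 0.89, did not pass. Glucocorticoid-responsive genes (12 of 18, median 0.26, adjusted p = 0.0930) with Zbtb16 at 1.09 and Cdkn1a at 0.92 did not pass. The EGF receptor family and its ligands (4 of 8, median -0.12, adjusted p = 0.576) with Nrg1 at 1.02 and Hbegf at 0.57 did not pass. Unfolded protein response genes, whose median was 0.00718 with library-size scaling (8 of 18, median -0.04, adjusted p = 0.457) with Ppp1r15a at -0.94 and Pdia4 at -0.54 did not pass. Cholesterol biosynthesis genes (7 of 18, median -0.28, adjusted p = 0.147) with Fdps at -0.62 did not pass. Apoptosis and p53 target genes, whose median was 0.00789 with RLE scaling (7 of 15, median -0.02, adjusted p = 0.315) with Pmaip1 at 0.97 did not pass. Axon guidance genes (14 of 21, median 0.21, adjusted p = 0.0930) with Plxna2 at 0.74 and Robo1 at 0.45 did not pass. Perineuronal net and matrix genes (8 of 12, median 0.21, adjusted p = 0.151) with Hapln2 at -1.26 did not pass. Ncan in this list averaged 235 ± 166 CPM in sgRosa and 541 ± 102 CPM in sgEgfr (SD, n = 3 each). Ionotropic glutamate receptors (13 of 15, median 0.21, adjusted p = 0.105) with Grin2a at 1.23 and Grik4 at -0.60 did not pass. Metabotropic glutamate receptors (5 of 7, median 0.21, adjusted p = 0.504) with Grm5 at 0.44 and Grm4 at -0.48 did not pass, nor did monoamine, opioid and cannabinoid receptors (8 of 11, median 0.25, adjusted p = 0.107) with Cnr1 at 0.81 and Drd1 at -0.73. For the endothelial, basolateral amygdala, hypothalamus and thalamus, EGF receptor family and apoptosis lists the median, mean and test differed in sign. For interferon-stimulated genes the difference of the list means was 0.04 (SE 0.47), so a shift in either direction stays possible. Grin2a averaged 1.03 ± 1.14 CPM in sgRosa, near the floor.

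**Figure D3:**
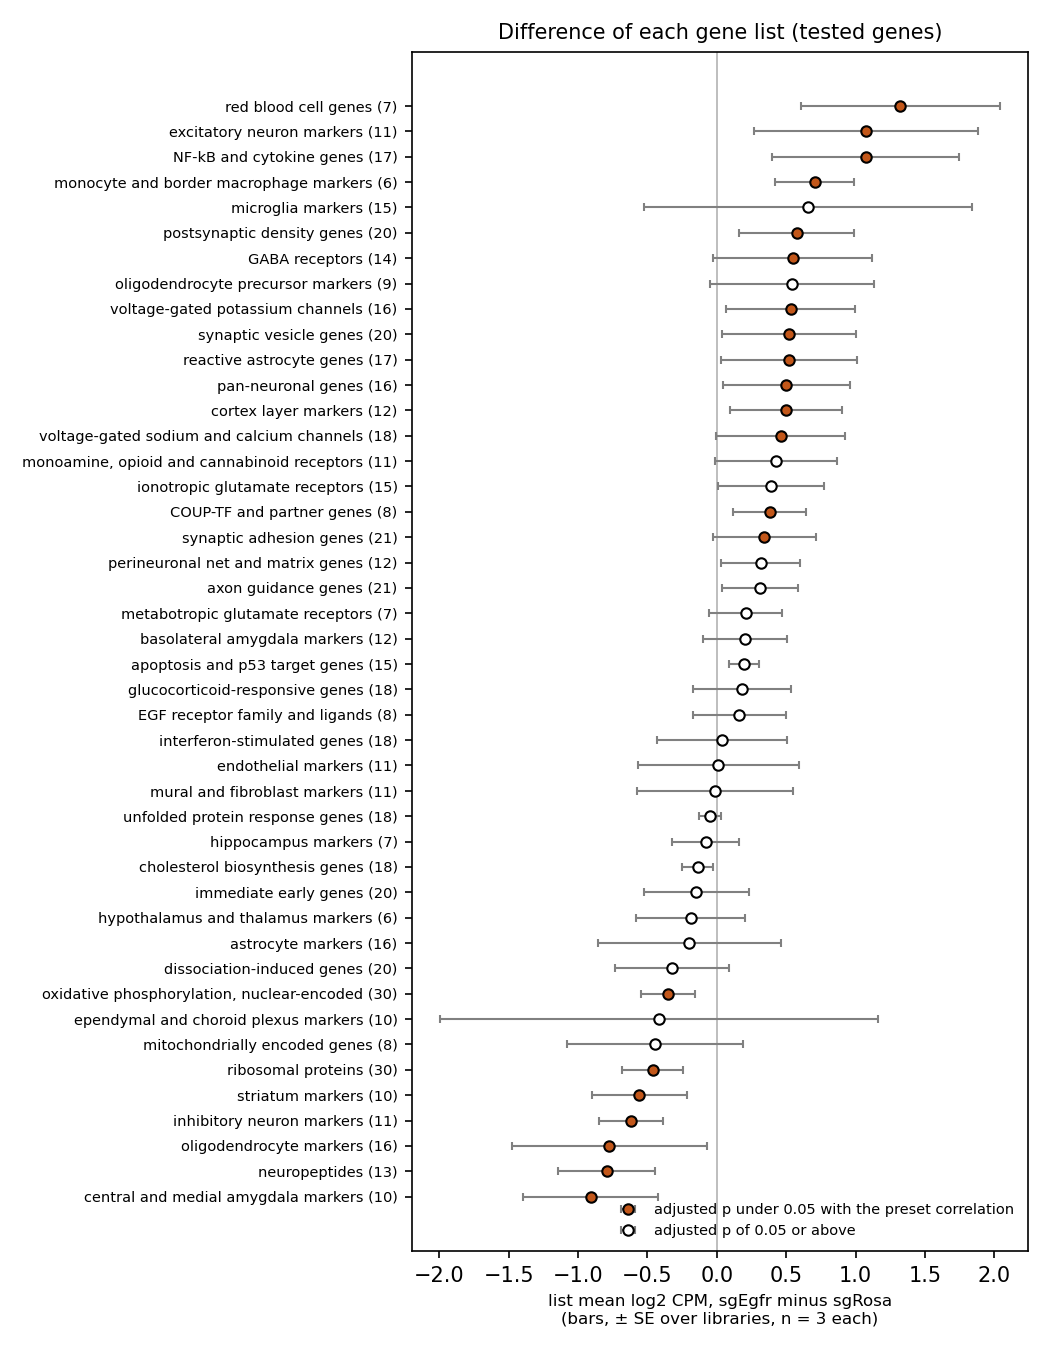
Difference of the list mean log2 CPM between sgEgfr and sgRosa for 44 lists, with bars for ± 1 SE over 3 libraries per group and the number of tested genes in brackets; filled points passed an adjusted p of 0.05 with the preset correlation. The ribosomal protein difference is -0.46 and the excitatory neuron difference 1.08.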

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

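The alternatives chosen only after the data were seen were 3: the pan-neuronal covariate, leaving out sgRosa replicate 3 and sgEgfr replicate 1, and removal of the length trend. The edgeR counts of 0 higher and 0 lower genes held under all 3. They also held under every alternative fixed in advance except DESeq2, which gave 31 higher and 2 lower genes. In the simulated counts, where 200 genes were changed, DESeq2 made 31 false calls, against 12 for the quasi-likelihood test and 8 for limma-voom. Those numbers do not estimate the false calls in the real counts. The cause of the difference in the real counts was not tested. The smallest adjusted p over these edgeR and limma-voom fits ranged from 0.117 without sgRosa replicate 3 to 0.999 without sgEgfr replicate 1. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.03, 0.48 and 0.28. For replicates 2 and 3 the same number gave the highest correlation, while sgRosa replicate 1 correlated best with sgEgfr replicate 2 (0.08). These values do not settle whether the samples are paired. With a replicate block the counts were 0 and 0 genes and 26 lists. The block gave 1316 genes at an unadjusted p under 0.05 by edgeR, against 811 without it, and a smallest adjusted p of 0.203. The log2 fold change of Nr2f2 ranged from 0.81 to 1.04 over all alternatives, with adjusted p from 0.0381 (DESeq2) to 0.999.

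The count of 21 lists became 0 with an estimated correlation, which widens the null for correlated genes by construction, and 0 with fry, which tests a list by itself. A simulated list of 20 independently drawn genes shifted by 1 log2 unit also did not pass camera with an estimated correlation (adjusted p = 0.186). A list that does not pass that test here may therefore still be shifted. Leaving out each library in turn gave between 12 and 25 lists, with 12 without sgRosa replicate 1. RLE scaling gave 20, the stricter filter 18 of 43 tested lists, the pan-neuronal covariate 14, leaving out sgRosa replicate 3 and sgEgfr replicate 1 gave 25, and removing the length trend 18. Under the pan-neuronal covariate 13 of the 21 lists lost the call and 8 kept it. Of the 13, 7 kept their direction: excitatory and striatum markers (adjusted p = 0.272), central and medial amygdala markers (adjusted p = 0.395), postsynaptic genes (adjusted p = 0.635), COUP-TF genes (adjusted p = 0.715), cortex markers (adjusted p = 0.737) and potassium channels (adjusted p = 0.779). The other 6 turned: pan-neuronal, oligodendrocyte and synaptic vesicle genes (adjusted p = 0.875), GABA receptors (adjusted p = 0.827), and sodium and calcium channels and synaptic adhesion genes (adjusted p = 0.798). The pan-neuronal result follows from the covariate's construction.

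Of 2197 recomputed log2 fold changes of the 123 genes that the naming rules took, 2169 kept their direction and stayed below the threshold, 15 passed under DESeq2 and 13 turned sign, none of them past the threshold. Without 1 library the value of 55 of the 123 genes fell by over 1.5 times or turned. Under the covariate Aqp4 was 0.26, Ly6c1 0.11 and Grm5 -0.0683. Without one library the ranges that crossed 0 were -1.16 to 0.95 for Egfr, -0.85 to 0.39 for Aqp4, -2.39 to 0.52 for Gjb6, -1.48 to 0.10 for Cldn5, -1.14 to 0.38 for Ly6c1, -1.87 to 0.0832 for Foxj1, -2.93 to 0.0214 for Ccdc153, -0.83 to 0.00709 for Grm4 and -0.00440 to 0.82 for Hbegf; the cause was not tested beyond the library left out.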

Other observations

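The first principal component of the libraries did not separate the groups. It took 43.5% of the variance and placed sgRosa replicate 3 (44.2) beside sgEgfr replicates 3 (37.6) and 1 (22.5), apart from sgEgfr replicate 2 (-3.70) and sgRosa replicates 2 (-28.6) and 1 (-72.0). The choroid plexus transcript Ttr, chosen after its values were seen, was at 3052 CPM in sgRosa replicate 3 and 1852 CPM in sgEgfr replicate 1 and at or below 28.1 CPM in the other 4 libraries. The myelin transcript Mbp, also chosen after its values were seen, reached 7110 CPM or more in every library, although the kit enriches neurons.

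Of the tests below, those of the neuronal share for the neuronal lists and for Nr2f2, of the RNA of other cells, of the dissection, of endothelial RNA and of the oxidative phosphorylation genes were chosen after the result was seen. The pan-neuronal covariate and the removal of the length trend, used in other tests below, were also chosen after seeing the data. The 10 splits of the 6 libraries into 2 groups of 3 are too few for a share under 0.05. By edgeR the real split gave 0 genes, as many as or fewer than each of the 10 splits, and the highest other split gave 587; at an unadjusted p under 0.05 the real split gave 811, the highest other 3222, and 2 of 10 gave as many. DESeq2 gave 33 for the real split and 1316 for the highest other, with 2 of 10 as large, and the preset list test gave 21 and 26, with 4 of 10 as large. The split with 587 genes sets sgRosa replicates 1 and 2 and sgEgfr replicate 2 against the other libraries, which points to a structure of the samples other than the guide.

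With the preset correlation 8 lists of neuronal genes passed toward higher and oligodendrocyte markers toward lower expression in sgEgfr, and with an estimated correlation none did (adjusted p of 0.691 or 0.705). With total counts made equal by thinning, the median log2 fold change of the excitatory markers was 0.84 against 0.82 before. The SD of 0.04 covers the 10 thinning draws and not the spread between libraries. Random thinning keeps the expected share of each gene in a library, so it could hardly have moved this median. The test therefore does not decide on sequencing depth or on library differences that go along with it. For an alike fall of the RNA of all other cells, 8 lists were taken relative to the oligodendrocyte markers. The red blood cell genes, picked for the highest ratio to its error, differed by 2.10 (SE 0.433) with separated groups, and the precursor markers by 1.32 (SE 0.637), also separated. The groups overlapped for the monocyte (1.48, SE 0.758), microglia (1.43, SE 1.09), astrocyte (0.57, SE 0.57), endothelial (0.79, SE 0.55), mural (0.76, SE 0.60) and ependymal lists (0.36, SE 1.90). A list picked as the most extreme of 8 does not decide the question, so an alike fall stays open. A different share of neuronal RNA goes with 5 lists of synaptic and channel genes. Without the genes they share with the pan-neuronal list and relative to its mean, these differed by 0.0200 (SE 0.05). Such a share stays open for the excitatory markers, which differed by 0.58 (SE 0.36). The inhibitory markers differed by -1.12 (SE 0.65) and kept their preset call with that mean as a covariate. With an estimated correlation no list passed camera under that covariate (smallest adjusted p = 0.755). A lower share of oligodendrocyte RNA alone, a different mix of tissue in the dissection, with cortex minus striatum markers differing by 1.05 (SE 0.70), and an untested effect of the guide on neurons also stay open.

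Ribosomal protein and oxidative phosphorylation genes passed camera toward lower expression in sgEgfr with the preset correlation and not with an estimated one (adjusted p = 0.691 for both). The SEs below are those of the group difference in the list's mean log2 CPM under the same correction. They are not errors of the medians, so a margin of 1 SE is only a rough guide. With each library's trend on transcript length removed, the oxidative phosphorylation median was -0.11 (SE 0.15) against -0.34 before, which is consistent with a length bias, and the ribosomal median was -0.24 (SE 0.19) against -0.48, which leaves it open. With the pan-neuronal mean as a covariate the oxidative phosphorylation median was -0.43 (SE 0.21), further from 0 than before. The preset call was kept, while 6 other lists turned direction. This median lay by more than 1 SE outside the range that a different share of neuronal RNA predicts. That margin was set after the value was seen, and the first margin left the reading open, so such a share is not excluded as the whole cause. For the ribosomal genes, at -0.35 (SE 0.22) with the call kept, a different share of neuronal RNA and an untested effect of the guide cannot be told apart, because the error reaches the range within 0.15 of 0 that the share predicts. Both lists also kept the preset call with the length trend removed, and an effect of the guide stays open for both.

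Nr2f2 was higher in all 3 sgEgfr libraries. The tables argue against a different share of neuronal RNA, since with the pan-neuronal mean as a covariate its log2 fold change was 0.89 (SE 0.20), and against a length bias, since with the length trend removed it was 0.90 (SE 0.21). With the endothelial mean as a covariate the log2 fold change of Nr2f2 was 0.94 (SE 0.20). That mean differed between the groups by only 0.0107 (SE 0.581), so the fit could hardly have moved Nr2f2. It does not decide on more endothelial RNA. The highest endothelial mean (8.33 log2 CPM) and the lowest Nr2f2 (52.0 CPM) were both in sgRosa replicate 1, which is a single library. RNA of other cell types that express Nr2f2, reads of the overlapping gene on the opposite strand and the dissection were not tested for this gene and stay open. An effect of the guide on neurons also stays open, as untested.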
